A study of Homo sapiens with 24 samples.

How the data were processed

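Total RNA from cultured cells and from peritoneal tumours was measured on Affymetrix HuGene 1.0 ST arrays, 1 sample per array, in 24 samples: 3 each of control and c-Fos cells of OVCAR8 and SKOV3, in culture and as tumours. Per the labels' protocols, cells were stably transfected and selected as clones, tumours came from immunodeficient mice injected in the peritoneal cavity (10 animals per group), RNA was extracted with Qiazol and labelled with the Ambion WT Expression Kit. The deposited values are log2 probe set levels made with the Affymetrix Expression Console and RMA, per the submitters' processing notes, and the versions of both and the genome build are not given in the sources used here. The values were taken as deposited, with no further normalization, and run from 1.53 to 14.17. Each array carried 33297 probe sets.

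Of the 33297 probe sets, 21214 had an entry in the probe annotation and 12083 had none. Of those annotated, 19460 had 1 gene symbol and were used, 1754 had several symbols and were left out, and 19429 were matched to a current symbol by gene ID. For the 769 genes with more than 1 probe set the one with the highest mean level was kept, which left 18417 genes. Gene names and gene order along chromosomes came from the RefSeq annotation of GRCh38.p14, used for nothing else. No pair of arrays was identical (smallest SD of a difference between 2 arrays 0.1819), and 0 columns of other series were present.

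Comparisons were made with limma 3.58.1 (lmFit and eBayes) under R 4.3.3 with the data.table package (version 1.17.8). A fit of the 12 culture arrays gave the effect of c-Fos in each line, the difference of the control lines and the difference of the c-Fos effects (OVCAR8 minus SKOV3). A fit of the 12 tumour arrays gave the same for tumours, and a fit of all 24 arrays gave tumour against culture in the controls of each line. Each fit has a mean per group and a variance shared by its groups. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over the 18417 genes. Each p-value given for a gene is such a limma p. The non-overlap count is the number of genes whose 3 values in 1 group all lie above or all below the 3 values of the other, and 10% of genes meet this by chance for 3 against 3 arrays. Shared genes were compared with the number expected under independence by Fisher's exact test, adjusted over 8 tests.

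The 25 gene lists were fixed by name: AP-1 subunits, immediate early genes, AP-1 target genes, selectins and endothelial adhesion receptors, selectin ligand scaffold proteins, sialyl Lewis glycan synthesis, integrins, laminins with collagens and matrix proteins, matrix proteases and inhibitors, epithelial junction genes, mesenchymal genes, ovarian lineage genes, ERBB2 amplicon genes, inflammatory cytokines and NF-kB targets, interferon-stimulated genes, cell cycle genes, hypoxia genes, cholesterol synthesis genes, unfolded protein and amino acid stress genes, ribosomal protein genes, and markers of fibroblasts, endothelium, leukocytes, mesothelium, and adipocytes with muscle and blood. They hold 705 genes, of which 654 were tested. Lists overlap: 13 of 22 AP-1 targets, 9 of 39 proteases, 7 of 29 mesenchymal genes, 7 of 18 endothelial markers, 6 of 38 matrix proteins, 5 of 17 fibroblast markers, 4 of 23 selectins and receptors, 4 of 36 hypoxia genes, 4 of 23 ovarian lineage genes, 3 of 20 scaffolds, 3 of 30 stress genes, 3 of 9 mesothelial markers, 2 of 33 epithelial genes, 2 of 38 cytokines, 1 of 25 integrins, 1 of 15 AP-1 subunits and 1 of 20 leukocyte markers are in another list, and 0 of the genes of the other 8 lists. Lists were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 25 lists. A list's direction in this test is relative to all other genes, so it can differ from the sign of the list's median.

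Genes were named by this rule: FOS in each comparison, then the 10 largest rises and 10 largest falls among called genes whose groups do not overlap (names of open reading frames, LOC entries, pseudogenes and small RNAs passed over), and from each list up to 4 called members with the largest change, or up to 2 as values only where none was called. For differences of effects it was the 5 largest in each direction. The text prints part of the genes so chosen. Groups, comparisons, tests, lists, the naming rule and the alternatives were set before the data were examined, apart from what follows. After the data were seen, fits without SKOV3 culture c-Fos replicate 1 were added for results where that array takes part only in the variance. The genes called in all 4 c-Fos comparisons and several tests of explanations, named where they are given, were also chosen then. The Fisher tests were narrowed from 24 to the 8 reported after all had been computed.

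The alternatives were: only the arrays of the compared groups in a fit, all 24 arrays in 1 fit, an intensity trend in eBayes, arrayWeights, quantile normalization on top, each array centred on its median, a filter against dim genes (above the 40th percentile on at least 3 arrays), the mean of the probe sets of a gene, a block for the replicate number, each array left out in turn, camera with an estimated correlation, and fry. The replicate numbers are not taken to pair samples, since no comparison had all 3 same-number correlations over 0.1.

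Arrays were grouped into 6 runs from marks in the sample labels. OVCAR8 control and c-Fos cultures were in different runs, all OVCAR8 tumours in 1 run, all SKOV3 cultures in 1 run, and the SKOV3 tumours in 1 run except control replicate 1. The fits were tested on simulated data with 100 genes changed by a log2 size of 1 and 100 by a size of 2 among 18417. For SKOV3 cultures 37 and 88 were recovered and 5 unchanged genes called, for SKOV3 tumours 84 and 99 with 11, and for SKOV3 tumour against culture 50 and 98 with 7, with 0 in the wrong direction. Camera called 1 simulated list (40 genes up by 0.5), not 1 unchanged, which gives no error rate. The median of each array was 6.82 to 7.10, so no array stands apart in level. SKOV3 culture c-Fos replicate 1 has a narrow range, with an SD of 1.5574 against 2.238 to 2.3635 elsewhere, and a correlation of 0.748 to 0.793 with the other arrays, which have at least 0.9224 among themselves. It was kept in all fits first given, as planned.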

Results

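Gene expression was measured on 24 single-colour oligonucleotide arrays, each giving a log2 level for the probe sets of the human genome. The samples form 8 groups of 3 arrays. They cover 2 human ovarian cancer cell lines, OVCAR8 and SKOV3, each as cultured cells and as tumours grown in the peritoneal cavity of immunodeficient mice. Each line is present as control cells and as cells made to overexpress c-Fos, the product of FOS and a subunit of the AP-1 transcription factor. After probe sets were matched to names, 18417 genes were compared. With 3 arrays per group the number of arrays limits precision. The labels do not say that the 3 arrays of a group come from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical. The c-Fos cells are stably transfected clones per the labels, and the number of clones is not given. Differences between clones and effects of c-Fos therefore cannot be told apart here.

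FOS itself was higher in the c-Fos samples of every group, which checks the sample labels. Its mean level was 8.63 ± 0.10 in SKOV3 control cultures and 11.05 ± 0.63 in SKOV3 c-Fos cultures, and 8.87 ± 0.14 and 10.96 ± 0.06 in the OVCAR8 cultures (mean ± SD, n = 3). In tumours it was 8.87 ± 0.10 and 11.52 ± 0.52 for SKOV3, and 7.93 ± 0.21 and 10.18 ± 0.41 for OVCAR8. Every c-Fos array, at 9.75 to 11.84, lay above every control array, at 7.72 to 8.99. FOS rose by a log2 change of 2.42 ± 0.26 in SKOV3 cultures (5.36-fold, adjusted p = 9.22e-05), and 2.09 ± 0.26 in OVCAR8 cultures (4.26-fold, adjusted p = 0.00131). In tumours it rose by 2.65 ± 0.24 in SKOV3 tumours (6.28-fold, adjusted p = 2.19e-06) and 2.25 ± 0.24 in OVCAR8 tumours (4.75-fold, adjusted p = 0.000124). The ± after a log2 change is the standard error throughout. The array signal does not separate the introduced coding sequence from the cells' own transcript.

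**Figure D1:**
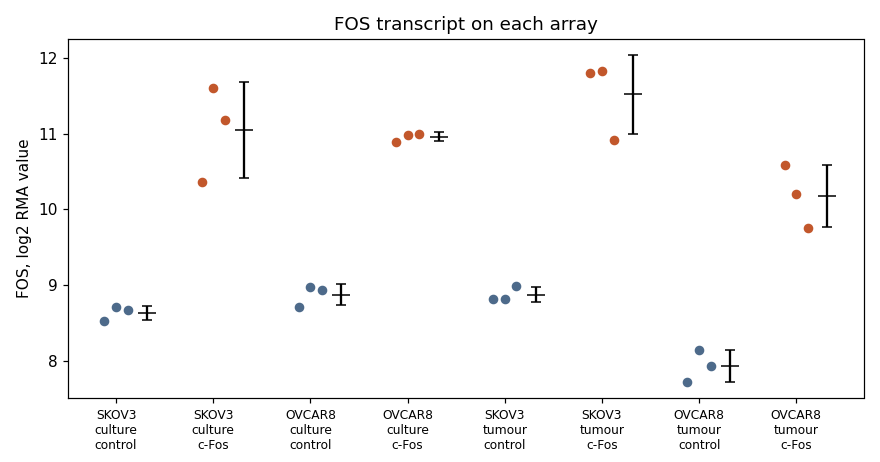
FOS level on each of the 24 arrays with the mean and SD of each group of 3. The c-Fos arrays span 9.75 to 11.84 and the control arrays 7.72 to 8.99.

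Control cultures of the 2 lines differed in single genes by up to 7.94 on the log2 scale. SKOV3 had far more CP, the copper-carrying ceruloplasmin (OVCAR8 minus SKOV3 −7.94 ± 0.33), SPP1, which encodes the adhesive phosphoprotein osteopontin (−7.41 ± 0.49), IDO1, a tryptophan-degrading enzyme (−6.02 ± 0.38), complement C3 (−5.86 ± 0.19) and DPP4, a cell-surface peptidase (−5.77 ± 0.28). OVCAR8 had more ANKRD1, a target of YAP signalling (6.02 ± 0.21), PLAC8 (5.88 ± 0.52), the cytokine receptor IL7R (5.18 ± 0.35) and PEG10 (4.86 ± 0.21). FOS itself differed by 0.24 (adjusted p = 0.685). The limma test called 3080 of 18417 genes, 1456 higher in OVCAR8 (891 of them at least 2-fold) and 1624 lower (1067 at least 2-fold). The non-overlap count was 12545 (68.1%, where 10% is the chance share for 3 v 3 arrays).

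Among adhesion genes in the control cultures, the differences went both ways. Of 23 selectins and endothelial adhesion receptors, 3 were higher in OVCAR8, 3 were lower and 17 did not pass (3 and 3 adjusted over the list alone). The higher ones were MCAM (3.75 ± 0.37), ICAM1, a ligand of leukocyte integrins (3.40 ± 0.22), and the junction receptor JAM2 (1.99 ± 0.21). Of 20 proteins that carry selectin ligands, 2 were lower in OVCAR8 (2 adjusted over the list alone), the larger being VCAN, the matrix proteoglycan versican (−3.87 ± 0.25). Of 47 genes that build sialyl Lewis glycans, 3 were higher and 8 lower (4 and 9 adjusted over the list alone), with GCNT3 (−4.01 ± 0.23), B3GNT5 (−2.56 ± 0.31) and the sialyltransferase ST3GAL6 (−1.84 ± 0.16) among the lower. Of 25 integrins, 3 were higher and 3 lower (4 and 3 adjusted over the list alone): ITGB8 was higher (1.95 ± 0.16), while ITGB6 (−3.47 ± 0.16), ITGA2 (−1.95 ± 0.30) and ITGB3 (−1.86 ± 0.35) were lower. None of these 4 lists passed as a whole in limma's camera test (adjusted p = 0.314 to 0.778). Matrix-degrading enzymes included MMP7 (−4.92 ± 0.53) and MMP2 (−4.79 ± 0.28), both lower in OVCAR8, in a list with 6 of 39 higher and 11 lower (6 and 14 adjusted over the list alone, camera adjusted p = 0.443). Of 38 matrix proteins 6 were higher and 6 lower (10 and 7 adjusted over the list alone, camera adjusted p = 0.587), with LAMA1 at 3.85 ± 0.20 and LAMB3 at −2.88 ± 0.22.

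Further lists separated the 2 lines in culture. Inflammatory cytokines and NF-kB targets were lower in OVCAR8 (15 of 38 lower, 3 higher; 17 and 3 adjusted over the list alone), for example CXCL1 (−4.01 ± 0.15) and IL1A (−3.73 ± 0.18), with adjusted p = 6.04e-06 by camera and adjusted p = 0.337 with an estimated correlation. The ERBB2 amplicon genes, which sit beside the growth factor receptor gene ERBB2 that SKOV3 is known to carry in extra copies, had 8 of 15 lower and 1 higher (9 and 1 adjusted over the list alone). ERBB2 (−3.59 ± 0.31) and PGAP3 (−2.29 ± 0.33) led them, with adjusted p = 1.38e-05 for the list, and adjusted p = 0.337 with an estimated correlation. Interferon-stimulated genes had 18 of 43 lower and 3 higher (22 and 3 adjusted over the list alone, adjusted p = 5.2e-05, and adjusted p = 0.337 with an estimated correlation), with OAS3 lower (−2.79 ± 0.29) and MX2 higher (4.62 ± 0.31). AP-1 target genes had 9 of 22 lower and 1 higher (10 and 1 adjusted over the list alone, adjusted p = 0.00586, and adjusted p = 0.337 with an estimated correlation), among them CXCL8 (−3.00 ± 0.24). Unfolded protein and amino acid stress genes were higher in OVCAR8 (10 of 30, 2 lower; 12 and 3 adjusted over the list alone; adjusted p = 0.000689, and adjusted p = 0.825 with an estimated correlation), for example ALDH1L2 (3.74 ± 0.17) and PHGDH (2.90 ± 0.19). Cholesterol synthesis genes (7 of 19 higher, 1 lower; the same counts adjusted over the list alone) had adjusted p = 0.00665, and adjusted p = 0.924 with an estimated correlation, with INSIG1 at 1.80 ± 0.22 and SC5D at −6.91 ± 0.47. Ribosomal protein genes (5 of 41 higher, 1 lower; 5 and 1 adjusted over the list alone) had adjusted p = 0.00646, and adjusted p = 0.931 with an estimated correlation. The remaining lists had adjusted p = 0.314 to 0.985, and for the epithelial, hypoxia, ovarian lineage and leukocyte lists the median and the mean lay on opposite sides of 0. SKOV3 culture c-Fos replicate 1 widens the variance shared by this fit: without that array, chosen after seeing the data, 9953 genes passed (5196 higher, 4757 lower), and all 3080 calls were kept. Lines and array runs coincide in these cultures, so run differences are part of these values.

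In control tumours the 2 lines differed in 8410 genes (3688 higher in OVCAR8, 972 at least 2-fold, and 4722 lower, 1910 at least 2-fold; non-overlap count 11044, chance share 10%). The interferon-induced IFI44L (5.97 ± 0.59), the receptor IL7R (5.75 ± 0.71), the peptidase CPA4 (5.50 ± 0.21) and the WNT inhibitor DKK1 (5.03 ± 0.66) were higher in OVCAR8. The matrix protease MMP7 (−7.20 ± 0.27), SPP1 (−6.93 ± 0.29), DPP4 (−5.98 ± 0.15), CP (−5.85 ± 0.18) and the stress cytokine GDF15 (−5.43 ± 0.12) were lower. FOS was lower by 0.94 ± 0.24 (adjusted p = 0.00557). Interferon-stimulated genes, lower in OVCAR8 in culture, were higher in OVCAR8 tumours (28 of 43 higher, 5 lower; 28 and 5 adjusted over the list alone; adjusted p = 1.21e-06, and adjusted p = 0.809 with an estimated correlation), with IFI44 at 4.29 ± 0.51 and IFITM1 at 3.76 ± 0.28. Matrix proteins (19 of 38 higher, 5 lower; 21 and 5 adjusted over the list alone) had adjusted p = 0.00042, and adjusted p = 0.394 with an estimated correlation, with TNC (4.41 ± 0.20), FBN2 (4.10 ± 0.20) and THBS1 (3.42 ± 0.30). Mesenchymal genes (17 of 29 higher, 3 lower; 18 and 3 adjusted over the list alone) had adjusted p = 0.00033, and adjusted p = 0.197 with an estimated correlation, with TGFB2 (3.64 ± 0.30) and CDH2, the N-cadherin gene (2.65 ± 0.24). The ERBB2 amplicon had 14 of 15 lower (15 adjusted over the list alone; adjusted p = 1.21e-06, and adjusted p = 0.108 with an estimated correlation), with GRB7 at −3.37 ± 0.17 and ERBB2 at −3.26 ± 0.14. Hypoxia genes had 17 of 36 lower and 4 higher (17 and 4 adjusted over the list alone; adjusted p = 0.0114, and adjusted p = 0.883 with an estimated correlation), with CA12 at −5.37 ± 0.25 and the glucose transporter SLC2A3 at 4.23 ± 0.15. All OVCAR8 tumours were in a run that held no SKOV3 tumour, so run differences are part of these values too.

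The adhesion lists of the control tumours again held genes of both directions and did not pass as wholes (adjusted p = 0.579 to 0.783). Selectins and endothelial adhesion receptors had 5 of 23 higher in OVCAR8 and 7 lower (6 and 7 adjusted over the list alone), with MCAM (3.45 ± 0.17), ICAM2 (1.84 ± 0.17) and JAM2 (1.57 ± 0.19). Selectin ligand scaffolds had 4 of 20 higher and 6 lower (4 and 6 adjusted over the list alone), with LGALS3BP at 1.22 ± 0.21 and VCAN at −2.87 ± 0.45. Sialyl Lewis synthesis genes had 8 of 47 higher and 13 lower (8 and 13 adjusted over the list alone), with GCNT3 (−3.91 ± 0.13) and B3GNT5 (−3.02 ± 0.19). Integrins had 4 of 25 higher and 6 lower (4 and 6 adjusted over the list alone), with ITGB3 (−3.94 ± 0.25), ITGA2 (−2.52 ± 0.19), ITGA6 (−1.99 ± 0.15) and ITGB8 (1.54 ± 0.22). Epithelial junction genes had 6 of 33 higher and 13 lower (7 and 13 adjusted over the list alone; camera adjusted p = 0.144), with E-cadherin CDH1 at −3.63 ± 0.20. Median and mean differ in sign for the selectin receptor, scaffold, protease, ovarian lineage, immediate early, leukocyte and stress lists. Fibroblast genes had 6 of 17 higher and 2 lower (6 and 2 adjusted over the list alone; camera adjusted p = 0.246). Endothelial genes had 7 of 18 higher and 2 lower (8 and 2 adjusted over the list alone; 0.155), and leukocyte genes 2 of 20 higher and 3 lower (2 and 2; 0.611). The remaining lists had adjusted p = 0.0702 to 0.936.

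SKOV3 cultures with c-Fos lost most of their CP, SPP1 and C3 transcripts. CP (−7.36 ± 0.33), SPP1 (−6.51 ± 0.49), C3 (−6.09 ± 0.19) and the steroid-metabolizing AKR1C3 (−6.03 ± 0.34) and AKR1C2 (−5.95 ± 0.32) fell. So did VCAN (−5.89 ± 0.25) and MAL2 (−5.68 ± 0.23). Each value is for 3 against 3 arrays, and SPP1 had the highest adjusted p of these falls, 6.03e-06. Rises were smaller: ANKRD30B (4.24 ± 0.45), the growth factor FGF5 (3.47 ± 0.21), the WNT effector LEF1 (2.68 ± 0.26) and CPA4 (2.59 ± 0.47). Limma called 1655 genes, 542 higher (194 at least 2-fold) and 1113 lower (815 at least 2-fold). The non-overlap count was 5301 (28.8%, chance share 10%).

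In the SKOV3 c-Fos cultures the selectin-related and integrin lists were not called as wholes (adjusted p = 0.152 to 0.301), and most of their members did not pass. Selectins and endothelial adhesion receptors had 1 rise and 3 falls of 23 (4 and 4 adjusted over the list alone), the rise being MCAM (2.12 ± 0.37). Selectin ligand scaffolds had 1 rise and 4 falls of 20 (2 and 4 adjusted over the list alone), with VCAN, LGALS3BP (−3.41 ± 0.24) and the mucin MUC1 (−1.31 ± 0.16) lower. Sialyl Lewis synthesis had 2 rises and 5 falls of 47 (2 and 6 adjusted over the list alone), with GCNT3 (−3.45 ± 0.23) and ST3GAL6 (−1.73 ± 0.16) lower. Integrins had 1 rise and 5 falls of 25 (1 and 7 adjusted over the list alone), with ITGB6 (−2.16 ± 0.16), ITGB8 (−2.13 ± 0.16) and ITGB4 (−1.54 ± 0.19) lower. Matrix proteins passed as a list, with 14 falls and 2 rises of 38 (16 and 3 adjusted over the list alone; adjusted p = 0.000787, and adjusted p = 0.43 with an estimated correlation): SPARC (−5.32 ± 0.20), the basement membrane proteins NID2 (−3.83 ± 0.29) and LAMB3 (−2.94 ± 0.22), and fibronectin FN1 (−2.85 ± 0.46). Matrix proteases had 8 falls and 2 rises of 39 (8 and 3 adjusted over the list alone, adjusted p = 0.14), with MMP7 (−4.02 ± 0.53), the collagenase MMP1 (−3.12 ± 0.19) and MMP2 (−2.80 ± 0.28) lower. Epithelial junction genes had 5 falls and 4 rises of 33 (7 and 6 adjusted over the list alone, adjusted p = 0.299), with the tight-junction gene CLDN1 (−3.62 ± 0.16) and the epithelial factor ELF3 (−3.32 ± 0.15) lower. Mesenchymal genes had 9 falls and 5 rises of 29 (10 and 6 adjusted over the list alone, adjusted p = 0.292), with FBN1 at −2.37 ± 0.26.

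In the SKOV3 c-Fos cultures 1 of the 25 lists stayed called with an estimated correlation, the interferon-stimulated genes. Interferon-stimulated genes had 24 falls and 1 rise of 43 (27 and 1 adjusted over the list alone), including the antigen-processing gene PSMB9 (−2.76 ± 0.15), IFI35 (−2.84 ± 0.22) and OAS1 (−2.15 ± 0.15). That list had adjusted p = 7.76e-13, and adjusted p = 0.0323 with an estimated correlation. Inflammatory cytokines and NF-kB targets had 16 falls and 0 rises of 38 (17 and 0 adjusted over the list alone; adjusted p = 4.59e-06, and adjusted p = 0.43 with an estimated correlation), with IL1A (−4.71 ± 0.18), SOD2 (−3.43 ± 0.35) and SAA2 (−3.14 ± 0.32). AP-1 target genes fell more often than they rose (6 against 1 of 22; 8 and 2 adjusted over the list alone; adjusted p = 0.0125, and adjusted p = 0.43 with an estimated correlation), with PLAU (−2.09 ± 0.32) and CXCL8 (−1.77 ± 0.24). Of 15 AP-1 subunits FOS rose and JUNB fell by 1.20 ± 0.22 (the same 2 adjusted over the list alone, camera adjusted p = 0.287). Immediate early genes had 3 rises and 2 falls of 26 (5 and 3 adjusted over the list alone; adjusted p = 0.707), with CCN1 at 1.93 ± 0.20. The ERBB2 amplicon had 3 falls of 15 (7 adjusted over the list alone; adjusted p = 0.000142, and adjusted p = 0.43 with an estimated correlation), with ERBB2 at −1.93 ± 0.31. Hypoxia genes had 6 falls and 2 rises of 36 (7 and 2 adjusted over the list alone; adjusted p = 0.0125, and adjusted p = 0.715 with an estimated correlation), with the carbonic anhydrase CA12 at −4.33 ± 0.16 and ADM at 2.34 ± 0.24. Ovarian lineage genes had 6 falls and 1 rise of 23 (6 and 1 adjusted over the list alone; adjusted p = 0.298), with MECOM (−3.64 ± 0.23) and the oestrogen receptor ESR1 (−1.98 ± 0.28). Cystine transporter SLC7A11 (−3.81 ± 0.34) fell in a stress list with 3 rises and 3 falls of 30 (6 and 8 adjusted over the list alone; adjusted p = 0.402). Markers of fibroblasts (4 rises and 5 falls of 17; 7 and 5 adjusted over the list alone), endothelium (0 and 5 of 18; 1 and 6), leukocytes (0 and 3 of 20; 0 and 3) and mesothelium (0 and 1 of 9; 0 and 1) did not pass as lists (adjusted p = 0.299 to 0.87). Nor did adipocyte, muscle and blood markers (0 of 16 in limma and 0 adjusted over the list alone, 2 higher at unadjusted p under 0.05; adjusted p = 0.0842) or ribosomal protein genes (1 fall of 41, 0 adjusted over the list alone; adjusted p = 0.14).

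SKOV3 culture c-Fos replicate 1 moves many of these values. Its SD over genes was 1.5574 against 2.238 to 2.3635 on the other 23 arrays. Without it, chosen after seeing the data, 7652 genes passed (4798 higher, 2854 lower), all 1655 calls were kept, and FOS rose by 2.77. The list counts then became 32 falls and 2 rises for interferon genes, 24 and 0 for cytokines, 19 and 7 for matrix proteins, 9 and 0 for the ERBB2 amplicon and 9 and 5 for AP-1 targets, all 5 lists still passing. The cell cycle list (1 fall of 50, 0 adjusted over the list alone, adjusted p = 0.000619) had 12 rises and 11 falls and adjusted p = 0.522 without the array, and adjusted p = 0.715 with an estimated correlation (0.336 to 0.715 over its alternatives). Cholesterol synthesis (2 falls and 1 rise of 19, 2 and 1 adjusted over the list alone, adjusted p = 0.0481; ACAT2 −2.26 ± 0.32) turned to the upward direction with adjusted p = 0.969, and adjusted p = 0.715 with an estimated correlation (0.292 to 0.969 over its alternatives). The hypoxia list had adjusted p = 0.244 without it (0.0747 to 0.715 over its alternatives), and endothelial markers (8 falls, 1 rise) passed at 0.00372, beside KDR at −1.46 ± 0.15. Leaving out SKOV3 culture c-Fos replicate 3 gave 6613 genes, and leaving out SKOV3 culture control replicates 1, 2 or 3 gave 946, 929 or 951. A fit of the 6 SKOV3 culture arrays alone called 343 genes and did not call CPA4, MCAM, MUC1, FN1, PLAU, JUNB or ERBB2. Median and mean differ in sign for the scaffold, integrin, protease, epithelial, mesenchymal, ovarian lineage, fibroblast, endothelial and mesothelial lists, where the median is above 0.

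OVCAR8 cultures with c-Fos gained a small set of strongly raised genes. The lipoprotein receptor OLR1 (4.84 ± 0.21), MMP1 (4.60 ± 0.19), the calcium-binding CALB1 (4.57 ± 0.15) and the junction protein AJAP1 (4.42 ± 0.40) rose. The ubiquitin ligase MARCHF4 (2.74 ± 0.18) rose too. CPA4 (−3.54 ± 0.47), the integrin chain ITGB8 (−3.22 ± 0.16), the thioredoxin inhibitor TXNIP (−3.19 ± 0.30) and MAL2 (−2.91 ± 0.23) fell. So did the guidance protein SEMA3E (−2.90 ± 0.22) and VCAN (−2.88 ± 0.25). The limma test called 461 genes, 144 higher (81 at least 2-fold) and 317 lower (212 at least 2-fold). The non-overlap count was 10063 (54.6%, chance share 10%), and 1975 genes had an unadjusted p under 0.05. Here group and array run coincide, so a run difference would count as an effect of c-Fos.

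Few adhesion genes passed in the OVCAR8 c-Fos cultures with all arrays kept. Integrins had 2 falls of 25 (2 adjusted over the list alone, camera adjusted p = 0.0545), with ITGB8 the larger. The scaffold list had 1 fall of 20, VCAN (1 adjusted over the list alone, adjusted p = 0.851). Selectins and endothelial receptors had 1 fall of 23 (3 falls and 1 rise adjusted over the list alone, adjusted p = 0.632), and sialyl Lewis synthesis 1 rise of 47 (1 adjusted over the list alone, adjusted p = 0.878). Matrix proteins had 4 falls and 2 rises of 38 (6 and 2 adjusted over the list alone, adjusted p = 0.0545), with TNC (−1.91 ± 0.19) and the basement membrane proteoglycan HSPG2 (−1.47 ± 0.19) lower. Mesenchymal genes had 5 falls and 2 rises of 29 (5 and 4 adjusted over the list alone, adjusted p = 0.0817), with CDH11 (−2.14 ± 0.29), smooth-muscle actin ACTA2 (−1.69 ± 0.14) and the transcription factor SNAI2 (−1.69 ± 0.21) lower. Epithelial genes had 3 falls and 1 rise of 33 (4 and 1 adjusted over the list alone, adjusted p = 0.878), with CLDN1 at −1.41 ± 0.16. Proteases had 3 rises, MMP1 among them, and 2 falls of 39 (3 and 3 adjusted over the list alone, adjusted p = 0.878). AP-1 targets had 2 rises of 22 (2 rises and 2 falls adjusted over the list alone, adjusted p = 0.0545).

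Metabolic lists passed in the OVCAR8 c-Fos cultures under the fixed correlation. Cholesterol synthesis had 3 falls of 19 (7 adjusted over the list alone), with INSIG1, a regulator of sterol synthesis, at −2.50 ± 0.22. As a list these genes had adjusted p = 6.35e-07, and adjusted p = 0.563 with an estimated correlation. Unfolded protein and amino acid stress genes had 8 falls of 30 (9 adjusted over the list alone), with the folate enzyme ALDH1L2 (−2.44 ± 0.17) and asparagine synthetase ASNS (−1.35 ± 0.16). Taken as a list, they had adjusted p = 0.000128, and adjusted p = 0.634 with an estimated correlation. Interferon-stimulated genes had 2 falls of 43 (2 adjusted over the list alone; adjusted p = 0.0316, and adjusted p = 0.563 with an estimated correlation), with SAMD9L at −2.02 ± 0.27. Hypoxia genes had 4 falls and 1 rise of 36 (5 and 2 adjusted over the list alone; adjusted p = 0.0316, and adjusted p = 0.749 with an estimated correlation), with INSIG2 at −1.10 ± 0.14. Cell cycle genes had a median of 0.31 with 0 of 50 called by limma (0 adjusted over the list alone, 6 higher at unadjusted p under 0.05) and adjusted p = 2.37e-05, and adjusted p = 0.749 with an estimated correlation. In cytokines IL1B fell by 1.73 ± 0.23 (2 rises, 1 fall of 38; 3 and 2 adjusted over the list alone; adjusted p = 0.0622). In fibroblast markers PDPN fell by 2.08 ± 0.15 (2 falls of 17; 3 falls and 1 rise adjusted over the list alone; adjusted p = 0.0622). AP-1 subunits had 2 rises of 15 (2 adjusted over the list alone, adjusted p = 0.162) and the ERBB2 amplicon 1 rise of 15 (1 adjusted over the list alone, adjusted p = 0.078). Immediate early genes had 0 of 26 called (4 at unadjusted p under 0.05; DUSP6 −1.10 ± 0.32, adjusted p = 0.125; list adjusted p = 0.851). The remaining lists had adjusted p = 0.219 to 0.91, and median and mean differ in sign for the immediate early, epithelial, leukocyte, protease, scaffold, sialyl Lewis and adipocyte lists.

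For OVCAR8 cultures, the narrow SKOV3 array acts only through the shared variance. Without it 5533 genes passed (2921 higher, 2612 lower), DUSP6 and CCN2 among them. The counts then were 12 falls of 19 cholesterol genes, 14 falls and 4 rises of 30 stress genes, 32 rises and 1 fall of 50 cell cycle genes, 13 falls and 5 rises of 43 interferon genes and 14 falls and 2 rises of 36 hypoxia genes. Leaving out any 1 OVCAR8 culture array gave 187 to 209 genes (control replicates 1, 2, 3: 187, 195, 209; c-Fos replicates 1, 2, 3: 202, 203, 208). FN1 (−2.21 ± 0.46, adjusted p = 0.0291) did not pass without any 1 of these 6 (0.116 to 0.131) or of the SKOV3 culture control arrays (0.0564 to 0.0575). The SE comes mostly from the narrow array, without which FN1 fell by the same −2.21 with an SE of 0.0835 (adjusted p = 8.95e-09).

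SKOV3 tumours with c-Fos gained EDIL3 and CPA4 transcripts and lost CP and SPP1. The matrix protein EDIL3 (6.05 ± 0.25), CPA4 (5.48 ± 0.21) and ANKRD30B (4.60 ± 0.23) rose. So did the protocadherin PCDH18 (4.43 ± 0.22), the muscle-filament protein MYPN (4.28 ± 0.28) and the vessel-guidance ligand EFNB2 (3.85 ± 0.17). CP (−6.26 ± 0.18), SPP1 (−5.89 ± 0.29), the protease inhibitor SLPI (−5.72 ± 0.24) and MMP7 (−5.66 ± 0.27) fell. C3 (−5.29 ± 0.35) and GDF15 (−5.09 ± 0.12) fell as well. Limma called 5178 genes, 2172 higher (485 at least 2-fold) and 3006 lower (957 at least 2-fold). The non-overlap count was 7016 (38.1%, chance share 10%). The muscle genes MYF5 and ASB5 also rose (5.23 ± 1.18 and 5.87 ± 0.66), driven by c-Fos replicates 1 and 3: MYF5 was 12.6, 6.1 and 12.5 in replicates 1, 2 and 3.

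Among the adhesion, junction and matrix lists of the SKOV3 tumours, only epithelial junction genes passed. Epithelial junction genes had 13 falls and 5 rises of 33 (13 and 5 adjusted over the list alone; adjusted p = 0.00207, and adjusted p = 0.149 with an estimated correlation), with MAL2 (−4.06 ± 0.36), ELF3 (−3.74 ± 0.14), CDH1 (−3.31 ± 0.20) and CLDN1 (−2.88 ± 0.26). Mesenchymal genes had 10 rises and 4 falls of 29 (10 and 5 adjusted over the list alone; adjusted p = 0.108), with SNAI2 (3.78 ± 0.17), TGFB2 (2.68 ± 0.30) and ZEB2 (2.07 ± 0.19). Integrins had 8 falls and 2 rises of 25 (8 and 2 adjusted over the list alone; adjusted p = 0.0776), with ITGB3 (−3.40 ± 0.25), ITGB8 (−3.12 ± 0.22), ITGB4 (−2.84 ± 0.27) and ITGA7 (1.74 ± 0.24). Selectin ligand scaffolds had 5 falls and 2 rises of 20 (8 and 3 adjusted over the list alone; adjusted p = 0.246), with VCAN (−4.12 ± 0.45), MUC1 (−2.59 ± 0.28), PODXL (−1.34 ± 0.21) and MUC16, the CA125 mucin (−1.10 ± 0.12). Sialyl Lewis synthesis had 10 falls and 4 rises of 47 (10 and 4 adjusted over the list alone; adjusted p = 0.282), with GCNT3 (−3.81 ± 0.13), B3GALT5 (−1.73 ± 0.23), ST3GAL6 (−1.70 ± 0.27) and B3GNT5 (1.80 ± 0.19). Selectins and endothelial adhesion receptors had 5 falls and 4 rises of 23 (5 and 4 adjusted over the list alone; adjusted p = 0.554), with JAM2 (2.80 ± 0.19), MCAM (2.26 ± 0.17) and ICAM1 (−1.26 ± 0.29). Matrix proteins had 11 falls and 8 rises of 38 (11 and 9 adjusted over the list alone; adjusted p = 0.491), with LAMB1 (−2.38 ± 0.17) and COL6A3 (3.79 ± 0.51). Proteases had 9 falls and 8 rises of 39 (10 and 10 adjusted over the list alone; adjusted p = 0.771).

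Hypoxia and inflammatory lists were lower in SKOV3 c-Fos tumours. Hypoxia genes had 25 falls and 2 rises of 36 (27 and 2 adjusted over the list alone), with CA12 (−3.72 ± 0.25), the chemokine receptor CXCR4 (−3.34 ± 0.24) and ANGPTL4 (−3.01 ± 0.50). Over the list camera gave adjusted p = 4.49e-09, and adjusted p = 0.408 with an estimated correlation. Cytokines and NF-kB targets had 17 falls and 2 rises of 38 (17 and 3 adjusted over the list alone), with SAA2 (−4.13 ± 0.25) and CCL2 (−3.47 ± 0.20). The list test gave adjusted p = 0.000152, and adjusted p = 0.408 with an estimated correlation. The ERBB2 amplicon had 9 falls of 15 (10 falls and 1 rise adjusted over the list alone), with GRB7 (−3.35 ± 0.17) and ERBB2 (−1.93 ± 0.14). Camera gave for this list adjusted p = 0.000146, and adjusted p = 0.149 with an estimated correlation. Interferon-stimulated genes split, with 10 falls and 7 rises of 43 (11 and 7 adjusted over the list alone; adjusted p = 0.929). AP-1 targets had 7 falls and 2 rises of 22 (9 and 3 adjusted over the list alone; adjusted p = 0.095). Immediate early genes had 7 falls and 3 rises of 26 (9 and 3 adjusted over the list alone; adjusted p = 0.285), with DUSP6, a brake on ERK signalling, at −3.83 ± 0.22. AP-1 subunits had 3 falls and 2 rises of 15 (3 and 2 adjusted over the list alone; adjusted p = 0.773), with JUNB at −1.31 ± 0.20. Ovarian lineage genes had 7 falls and 2 rises of 23 (8 and 2 adjusted over the list alone; adjusted p = 0.285), with MECOM (−3.27 ± 0.22) and ESR1 (−2.54 ± 0.15). Stress genes had 8 falls and 3 rises of 30 (8 and 3 adjusted over the list alone; adjusted p = 0.285), with SLC7A11 at −4.12 ± 0.62. Cell cycle genes had 10 falls and 4 rises of 50 (10 and 4 adjusted over the list alone; adjusted p = 0.378). Cholesterol genes had 4 falls and 1 rise of 19 (4 and 1 adjusted over the list alone; adjusted p = 0.35) and ribosomal protein genes 3 rises of 41 (2 adjusted over the list alone; adjusted p = 0.356). Median and mean differ in sign for the interferon, protease and ovarian lineage lists.

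Fibroblast markers in SKOV3 tumours with c-Fos had 8 rises and 1 fall of 17 (9 and 1 adjusted over the list alone), with COL1A2 (2.97 ± 0.18) and FAP (2.42 ± 0.25). In the list test they had adjusted p = 0.00742, and adjusted p = 0.408 with an estimated correlation. The adipocyte, muscle and blood list had 5 rises and 1 fall of 16 (6 and 1 adjusted over the list alone), with the muscle filament DES at 1.63 ± 0.37. For the list, camera gave adjusted p = 0.0445, and adjusted p = 0.408 with an estimated correlation. Endothelial (2 rises, 1 fall of 18; 1 and 1 adjusted over the list alone), leukocyte (3 and 1 of 20; 3 and 1) and mesothelial markers (1 and 1 of 9; 1 and 1) had adjusted p = 0.285 to 0.467, with ENG at 0.91 ± 0.20 and CD14 at 0.59 ± 0.12. Of the 17 fibroblast markers 5 are also in another list. SKOV3 tumour control replicate 1 was the only array of its run. Without it, the comparison lay within a single run and called 5239 genes.

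OVCAR8 tumours with c-Fos kept the CALB1, MMP1 and AJAP1 rises seen in culture and lost interferon-stimulated transcripts. CALB1 (6.32 ± 0.47), the organic anion transporter SLCO1B3 (4.56 ± 0.38) and MMP1 (3.26 ± 0.37) rose. MYPN (3.12 ± 0.28) and AJAP1 (2.67 ± 0.34) rose too. IFI44L (−3.57 ± 0.59), TNC (−2.92 ± 0.20), CPA4 (−2.88 ± 0.21) and TXNIP (−2.66 ± 0.26) fell. EDIL3 (−2.39 ± 0.25) fell as well. The limma test called 1409 genes, 622 higher (145 at least 2-fold) and 787 lower (214 at least 2-fold). The non-overlap count was 5534 (30.0%, chance share 10%). Leaving out OVCAR8 tumour control replicate 2, control replicate 3 or c-Fos replicate 2 gave 742, 637 or 906 genes.

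Among the 787 genes lower in OVCAR8 tumours with c-Fos were 27 interferon-stimulated genes and 13 matrix proteins. Interferon-stimulated genes had 27 falls and 0 rises of 43 (33 and 0 adjusted over the list alone, median −1.21), with IFI6 at −2.23 ± 0.30. As a group they had adjusted p = 2.33e-22, and adjusted p = 0.329 with an estimated correlation. Matrix proteins had 13 falls and 1 rise of 38 (15 and 1 adjusted over the list alone), with TNC, HSPG2 (−2.02 ± 0.26), FBN1 (−1.73 ± 0.27) and FN1 (−1.66 ± 0.24). As a list these genes had adjusted p = 2.53e-07, and adjusted p = 0.273 with an estimated correlation. Fibroblast markers had 4 falls of 17 (5 adjusted over the list alone), with COL1A1 (−1.53 ± 0.29) and PDPN (−1.05 ± 0.16). Taken as a list, they had adjusted p = 0.000984, and adjusted p = 0.329 with an estimated correlation. Mesenchymal genes had 5 falls and 1 rise of 29 (6 and 2 adjusted over the list alone), with CDH11 at −1.80 ± 0.16. Over the list camera gave adjusted p = 0.00742, and adjusted p = 0.329 with an estimated correlation. Hypoxia genes had 7 rises of 36 (7 adjusted over the list alone), with ADM (1.71 ± 0.22) and the glycolytic ALDOC (1.12 ± 0.24). The list test gave adjusted p = 0.000773, and adjusted p = 0.905 with an estimated correlation. AP-1 targets had 2 rises of 22 (5 rises and 1 fall adjusted over the list alone; adjusted p = 0.0389, and adjusted p = 0.75 with an estimated correlation). Ribosomal protein genes had 1 rise of 41 (0 adjusted over the list alone), a median of 0.26 and adjusted p = 3.49e-06, and adjusted p = 0.75 with an estimated correlation.

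Adhesion lists of the OVCAR8 tumours had few changed members and adjusted p = 0.81 to 0.875. Integrins had 1 rise, the laminin receptor chain ITGA6 (1.30 ± 0.15), and 2 falls of 25 (3 and 3 adjusted over the list alone). ITGB8 fell by 1.07 ± 0.22 (adjusted p = 0.01), and had adjusted p = 0.0547 without OVCAR8 tumour control replicate 2. Selectins and endothelial adhesion receptors had 2 rises and 1 fall of 23 (2 and 2 adjusted over the list alone), with ICAM2 at 1.29 ± 0.17. Sialyl Lewis synthesis had 4 rises and 1 fall of 47 (4 and 1 adjusted over the list alone), with B3GNT5 at 1.21 ± 0.19. Scaffolds had 2 falls of 20 (2 adjusted over the list alone), the larger being VCAN (−1.75 ± 0.45, adjusted p = 0.0303), which did not pass (adjusted p = 0.0547 to 0.119) whichever of the 6 OVCAR8 tumour arrays was left out. Epithelial genes had 4 rises and 1 fall of 33 (5 and 3 adjusted over the list alone; adjusted p = 0.244). Immediate early genes had 3 rises and 1 fall of 26 (4 and 1 adjusted over the list alone; adjusted p = 0.244), with EGR1 at −1.45 ± 0.24. Cytokines had 3 rises and 3 falls of 38 (4 and 5 adjusted over the list alone; adjusted p = 0.875), with CCL5 at −1.64 ± 0.18. Endothelial (1 rise of 18, 2 adjusted over the list alone) and leukocyte markers (1 rise of 20, 1 adjusted over the list alone) had adjusted p = 0.875, and the remaining lists 0.244 to 0.882. Median and mean differ in sign for the AP-1 subunit, endothelial, ovarian lineage, protease and adipocyte lists.

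**Figure D2:**
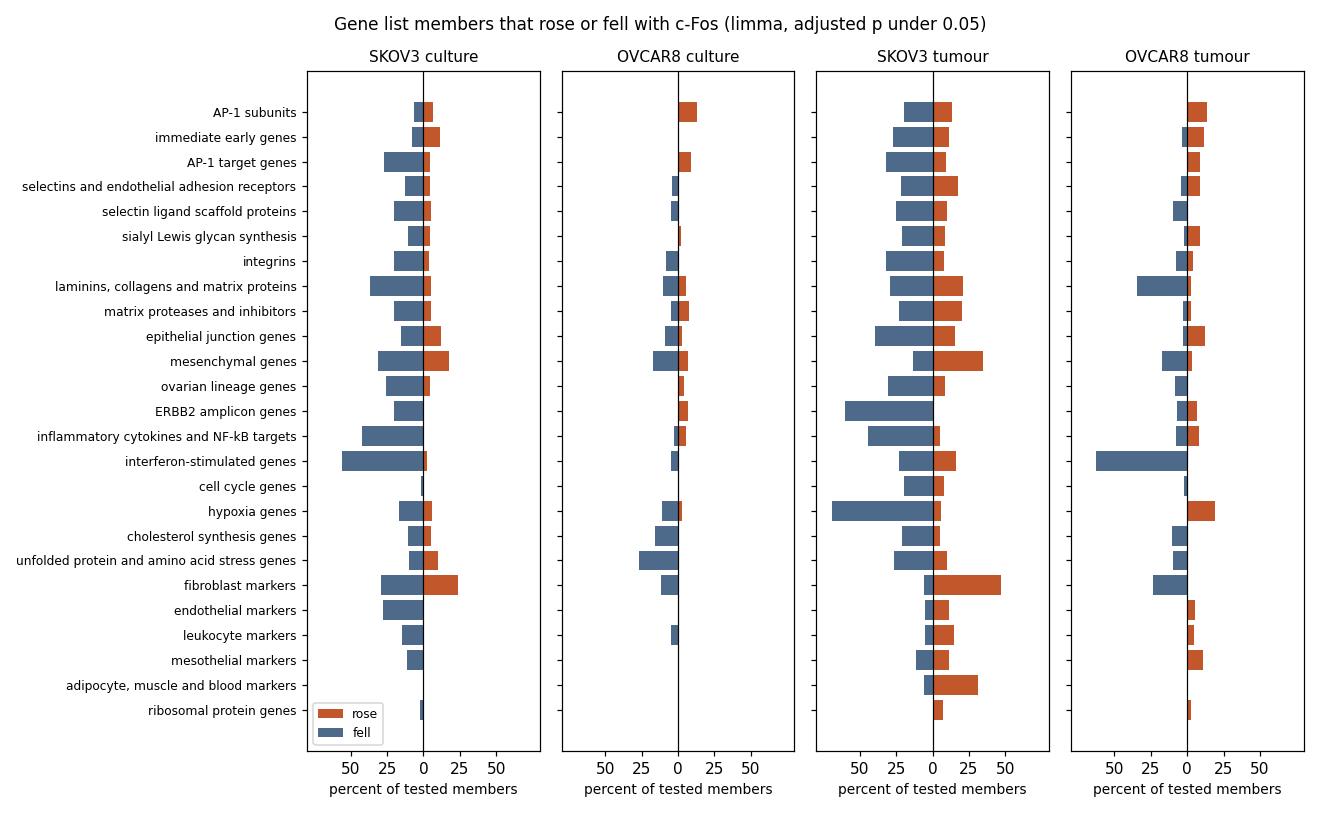
Percent of tested members of each of the 25 lists that rose or fell with c-Fos in the 4 comparisons. Interferon genes had 24 of 43 falls in SKOV3 cultures and 27 of 43 in OVCAR8 tumours, and hypoxia genes 25 of 36 falls in SKOV3 tumours.

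More genes fell with c-Fos in both lines than independence, which shared variances break, gives. In culture 116 genes fell in both lines against 19.2 expected (Fisher exact test, adjusted p = 3.19e-60) and 25 rose in both against 4.2 expected (adjusted p = 8.54e-13). In tumours 296 fell in both against 128.5 expected (adjusted p = 3.72e-49) and 107 rose against 73.4 expected (adjusted p = 4.91e-05). VCAN, CLDN1, MAL2, ITGB8 and IL1B fell in both cultures, and ADM and MARCHF4 rose. Between culture and tumour of the same line, SKOV3 shared 248 higher genes (63.9 expected, Fisher exact adjusted p = 1.11e-89) and 767 lower genes (181.7 expected). OVCAR8 shared 72 higher (4.9 expected, adjusted p = 6.19e-67) and 151 lower (13.5 expected, adjusted p = 6.28e-122). Without SKOV3 culture c-Fos replicate 1 the shared culture counts were 1196 higher (761.0 expected) and 792 lower (404.8).

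The effect of c-Fos differed between the lines for 909 genes in culture, 570 with a more positive effect in OVCAR8 and 339 with a more negative one. The largest differences (effect in OVCAR8 minus effect in SKOV3) were CALB1 (8.47 ± 0.21), MMP1 (7.72 ± 0.27), CP (7.63 ± 0.47), SPP1 (6.75 ± 0.69) and C3 (6.11 ± 0.27). CP, SPP1 and C3 had means of 4.31 to 6.13 in both OVCAR8 groups, under the dim level of 6.33, so they could hardly fall there. On the other side were CPA4 (−6.12 ± 0.66), LEF1 (−4.50), FGF5 (−4.50), ANKRD30B (−4.32) and the desmosomal DSC3 (−3.76). MMP1 and CPA4 changed in opposite directions: MMP1 rose in OVCAR8 and fell in SKOV3 cultures, and CPA4 fell in OVCAR8 and rose in SKOV3. FOS did not differ (−0.33 ± 0.37, adjusted p = 0.559, and adjusted p = 0.00785 at −0.68 without the narrow SKOV3 array). In OVCAR8 cultures group and run coincide, so a run difference would enter these values. The effect was more positive in OVCAR8 for interferon genes (12 of 43 and 0 the other way; 15 and 1 adjusted over the list alone; adjusted p = 1.46e-07, and adjusted p = 0.15 with an estimated correlation), which had fallen in SKOV3. The same held for cytokines (12 of 38 and 0; 16 and 0 adjusted over the list alone; adjusted p = 1.46e-07, and adjusted p = 0.263 with an estimated correlation). The ERBB2 amplicon (4 of 15 and 0; 5 and 0 adjusted over the list alone; adjusted p = 2.02e-05, and adjusted p = 0.394 with an estimated correlation) and AP-1 targets (3 of 22 and 1; 5 and 1 adjusted over the list alone; adjusted p = 0.000915, and adjusted p = 0.263 with an estimated correlation) lay on the same side. Cell cycle genes had 0 of 50 called by limma (0 adjusted over the list alone, 15 at unadjusted p under 0.05) and adjusted p = 1.46e-07, and adjusted p = 0.839 with an estimated correlation. The median over all genes was −0.12, and 0.04 after each array was centred, where 646 genes (73.5%) were more positive and 233 more negative against 62.7% in the fit first given. Without SKOV3 culture c-Fos replicate 1, 6362 genes passed (2798 positive, 3564 negative), and without c-Fos replicate 3 of the same group 2911. Leaving out OVCAR8 culture control replicates 1, 2 or 3 gave 541, 545 or 537, OVCAR8 culture c-Fos replicates 549, 556 or 537, and SKOV3 culture control replicates 568, 563 or 567.

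In tumours the effect of c-Fos differed between the lines for 3178 genes, 1955 more positive in OVCAR8 and 1223 more negative. CALB1 (7.97 ± 0.67), SLPI (6.56 ± 0.34), CP (6.15), SPP1 (5.97) and MMP7 (5.70) lay on the positive side, and EDIL3 (−8.44 ± 0.36), CPA4 (−8.35 ± 0.29), ASB5 (−5.76) and the RNA-binding RBMS3 (−5.73) on the negative side. CP, SPP1 and MMP7, at means of 4.76 to 5.86 in both OVCAR8 groups, could hardly fall there. MYF5 (−5.32) passed with adjusted p = 0.0434, but not when any tumour array other than SKOV3 c-Fos replicate 2 was left out (adjusted p up to 0.0956, without SKOV3 c-Fos replicate 1). FOS did not differ (−0.40 ± 0.34, adjusted p = 0.467). Hypoxia genes were more positive in OVCAR8 (20 of 36 and 0 the other way; 26 and 0 adjusted over the list alone; adjusted p = 8.62e-13, and adjusted p = 0.259 with an estimated correlation). Epithelial junction genes were more positive too (14 of 33 and 3; 14 and 3 adjusted over the list alone; adjusted p = 0.000115, and adjusted p = 0.0553 with an estimated correlation), among which CDH1 and MAL2 had fallen in SKOV3 tumours. The same held for cytokines (15 of 38 and 2; 17 and 3 adjusted over the list alone; adjusted p = 0.000306, and adjusted p = 0.389 with an estimated correlation) and for the ERBB2 amplicon (6 of 15 and 0; 7 and 0 adjusted over the list alone; adjusted p = 0.000741, and adjusted p = 0.16 with an estimated correlation). AP-1 targets (7 of 22 and 1; 8 and 1 adjusted over the list alone; adjusted p = 0.00589, and adjusted p = 0.414 with an estimated correlation) and integrins (7 of 25 and 2; 7 and 2 adjusted over the list alone; adjusted p = 0.0292, and adjusted p = 0.178 with an estimated correlation) lay on the same side. Interferon genes were more negative in OVCAR8 (17 of 43 and 1 the other way; 22 and 2 adjusted over the list alone; adjusted p = 1.73e-07, and adjusted p = 0.467 with an estimated correlation). So were mesenchymal genes (12 of 29 and 2; 13 and 2 adjusted over the list alone; adjusted p = 0.000741, and adjusted p = 0.16 with an estimated correlation). Fibroblast markers (8 of 17 and 1; 8 and 1 adjusted over the list alone; adjusted p = 6.07e-05, and adjusted p = 0.16 with an estimated correlation) and matrix proteins (12 of 38 and 6; 15 and 7 adjusted over the list alone; adjusted p = 0.026, and adjusted p = 0.414 with an estimated correlation) were more negative as well.

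**Figure D3:**
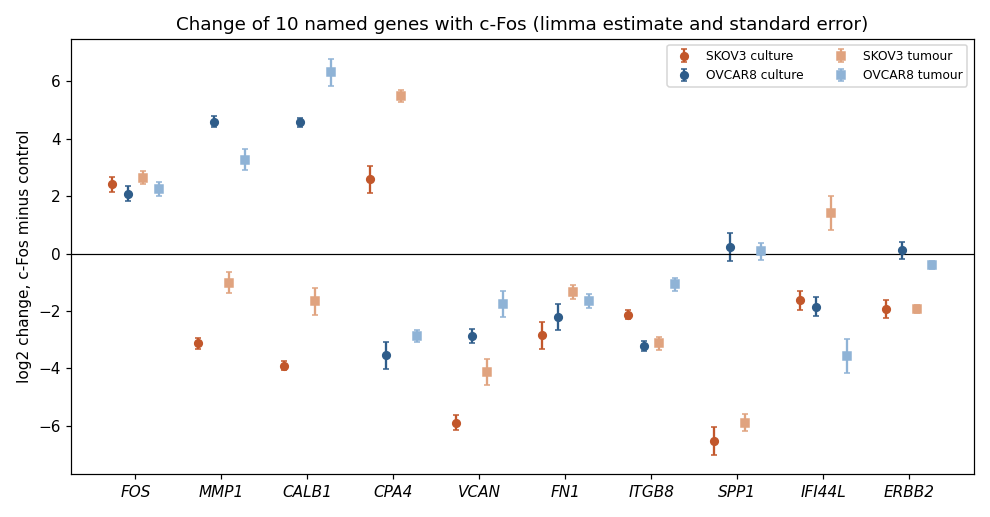
Log2 change with c-Fos and its standard error for 10 named genes in the 4 comparisons. MMP1 changed by 4.60 in OVCAR8 cultures and −3.12 in SKOV3 cultures, while VCAN fell in all 4.

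SKOV3 control tumours differed from SKOV3 control cultures by a gain of hypoxia-linked and epithelial transcripts. The intestinal protease TMPRSS15 (4.80 ± 0.31), the retinal dehydrogenase ALDH1A1 (3.90 ± 0.21), the receptor ERBB4 (3.78 ± 0.27), the chemokine CCL2 (3.57 ± 0.30) and CXCR4 (3.31 ± 0.33) were higher in tumours. AMTN (−6.22 ± 0.24), EDIL3 (−4.78 ± 0.42), the cadherin CDH6 (−4.47 ± 0.22) and the adhesive THBS1 (−3.78 ± 0.34) were lower. FOS differed by 0.24 (adjusted p = 0.766). Hypoxia genes had 18 rises of 36 (21 adjusted over the list alone), with DDIT4 (2.49 ± 0.21) and ADM (2.26 ± 0.24). Camera gave for this list adjusted p = 4.84e-17, and adjusted p = 0.145 with an estimated correlation. Epithelial junction genes had 11 rises and 1 fall of 33 (15 and 2 adjusted over the list alone), with CLDN4 (2.17 ± 0.17) and EPCAM (2.01 ± 0.25). In the list test they had adjusted p = 0.00023, and adjusted p = 0.05 with an estimated correlation. Mesenchymal genes had 7 falls and 2 rises of 29 (9 and 2 adjusted over the list alone), with SNAI2 (−3.21 ± 0.20) and CDH2 (−2.18 ± 0.28). For the list, camera gave adjusted p = 0.000175, and adjusted p = 0.05 with an estimated correlation. Matrix proteins had 9 falls and 1 rise of 38 (10 and 2 adjusted over the list alone; adjusted p = 0.000525, and adjusted p = 0.19 with an estimated correlation). Cell cycle genes had 10 falls of 50 (21 adjusted over the list alone; CENPE −1.46 ± 0.29; adjusted p = 7.86e-15, and adjusted p = 0.438 with an estimated correlation). Among adhesion genes ICAM1 (1.98 ± 0.28), ITGB3 (2.25 ± 0.32) and ITGB8 (1.49 ± 0.21) rose and ITGB6 (−1.46 ± 0.23) fell, in lists with 2 rises of 23 selectins and receptors and 3 rises and 3 falls of 25 integrins (the same counts adjusted over the list alone; camera adjusted p = 0.908 and 0.642).

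No list of cell type markers was called higher in the SKOV3 control tumours, but human probe sets may miss mouse host tissue. Single members rose, LRRN4 (1.39 ± 0.26) with 1 rise and 1 fall of 9 mesothelial markers (1 and 2 adjusted over the list alone; adjusted p = 0.246), and CFD (0.55 ± 0.15) as 1 of 16 adipocyte, muscle and blood markers (1 adjusted over the list alone; adjusted p = 0.865). Fibroblast markers had 3 falls of 17 (4 adjusted over the list alone; adjusted p = 0.0638) and leukocyte markers 1 fall of 20 (1 adjusted over the list alone; adjusted p = 0.908). Endothelial markers had 3 falls of 18 (3 adjusted over the list alone), with KDR at −1.92 ± 0.12. As a group they had adjusted p = 0.00336, and adjusted p = 0.747 with an estimated correlation. Interferon genes had 4 falls and 1 rise of 43 (8 and 1 adjusted over the list alone; adjusted p = 0.00401, and adjusted p = 0.764 with an estimated correlation), with SAMD9L at −2.43 ± 0.30. The other lists had adjusted p = 0.0638 to 0.973. For the scaffold, selectin receptor, leukocyte and ovarian lineage lists the test pointed down while median and mean were above 0, and for cholesterol genes the median and the mean differ in sign. Limma called 1623 genes, 1042 higher (456 at least 2-fold) and 581 lower (323 at least 2-fold), with a non-overlap count of 7663 (41.6%, chance share 10%). Without SKOV3 culture c-Fos replicate 1, which takes part only in the variance, 4797 genes passed (2907 higher, 1890 lower). The list counts were 25 rises for hypoxia, 17 rises and 2 falls for epithelial, 11 falls and 3 rises for mesenchymal, 35 falls for cell cycle and 11 falls and 2 rises for matrix genes. Leaving out SKOV3 culture control replicate 1 or 3 gave 1023 or 1040 genes. Culture and tumour arrays were run apart, so site and run cannot be told apart in either line.

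OVCAR8 control tumours differed from OVCAR8 control cultures above all by interferon-stimulated genes. Of 43, 31 rose and 0 fell (35 and 0 adjusted over the list alone), among them IFI44L (4.61 ± 0.53), IFITM1 (3.98 ± 0.38), OAS2 (3.63 ± 0.44), IFIT1 (3.45 ± 0.38) and MX1 (3.35 ± 0.44). As a list these genes had adjusted p = 2.93e-55, and adjusted p = 0.00853 with an estimated correlation. C3 (3.90 ± 0.31), TNC (2.56 ± 0.20) and the chemokine CCL5 (2.50 ± 0.27) rose too. The activin subunit INHBA (−3.26 ± 0.43), SEMA3E (−3.17 ± 0.20), IL1B (−2.98 ± 0.34), MMP1 (−2.03 ± 0.32), EGR1 (−1.49 ± 0.26) and CCN1 (−1.32 ± 0.17) fell. FOS was at −0.94 ± 0.26 (adjusted p = 0.056, and 0.00256 without SKOV3 culture c-Fos replicate 1). ITGA6 fell (−1.36 ± 0.27) and ITGB8 rose (1.08 ± 0.21), the only 2 called of 25 integrins (2 adjusted over the list alone; camera adjusted p = 0.537). Of 23 selectins and endothelial adhesion receptors 0 passed in limma (0 adjusted over the list alone, 3 at unadjusted p under 0.05; adjusted p = 0.922).

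Smaller list shifts in the OVCAR8 control tumours were lost with an estimated correlation. Fibroblast markers had 3 rises and 2 falls of 17 (6 and 2 adjusted over the list alone; adjusted p = 0.000498, and adjusted p = 0.301 with an estimated correlation), with PDGFRB (1.21 ± 0.20), COL1A2 (0.96 ± 0.18) and PDPN (−1.07 ± 0.16). Leukocyte markers had 0 of 20 called by limma (0 adjusted over the list alone, 4 at unadjusted p under 0.05), adjusted p = 0.0244, and adjusted p = 0.675 with an estimated correlation. Hypoxia genes had 4 rises and 1 fall of 36 (6 and 1 adjusted over the list alone; adjusted p = 0.00045, and adjusted p = 0.599 with an estimated correlation), with DDIT4 at 1.46 ± 0.21. Cytokines had 3 rises and 2 falls of 38 (8 and 2 adjusted over the list alone; adjusted p = 0.000488, and adjusted p = 0.593 with an estimated correlation). Matrix proteins had 5 rises and 1 fall of 38 (5 and 1 adjusted over the list alone; adjusted p = 0.00197, and adjusted p = 0.41 with an estimated correlation), and stress genes had 4 falls and 1 rise of 30 (5 and 1 adjusted over the list alone; ASNS −1.44 ± 0.24; adjusted p = 0.00197, and adjusted p = 0.599 with an estimated correlation). Cell cycle genes had 0 of 50 called by limma (0 adjusted over the list alone, 19 lower at unadjusted p under 0.05), adjusted p = 4.89e-08, and adjusted p = 0.599 with an estimated correlation. The other lists had adjusted p = 0.0941 to 0.934. The limma test called 575 genes, 243 higher (123 at least 2-fold) and 332 lower (173 at least 2-fold). The share higher was 42.3%, against 175 higher and 373 lower (31.9%) with each array centred and 277 and 570 (32.7%) after quantile normalization. The non-overlap count was 8957 (48.6%, chance share 10%). Without the narrow array 3119 genes passed (1035 higher, 2084 lower), ALCAM and PECAM1 among them. Of 43 interferon genes 35 rose, and of 50 cell cycle genes 27 fell. Leaving out OVCAR8 culture control replicates 1, 2 or 3 gave 258, 287 or 252 genes, and OVCAR8 tumour control replicates 327, 281 or 299.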

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

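The tests of OVCAR8 admixture, of dim genes, of host muscle and of MYF5 and ASB5 in culture were chosen only after the results were seen.

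The effect of c-Fos differed between the lines for 909 genes in culture and 3178 in tumours. In culture the largest differences (OVCAR8 minus SKOV3) were CALB1 8.47, MMP1 7.72, CP 7.63, SPP1 6.75 and C3 6.11, and CPA4 −6.12, LEF1 −4.50, FGF5 −4.50, ANKRD30B −4.32 and DSC3 −3.76. In tumours they were CALB1 7.97, SLPI 6.56, CP 6.15, SPP1 5.97 and MMP7 5.70, and EDIL3 −8.44, CPA4 −8.35, ASB5 −5.76, RBMS3 −5.73 and MYF5 −5.32. Both OVCAR8 groups were dim (means under 6.33, the 40th percentile of all values) for CP and SPP1 at both sites, C3 in culture and MMP7 in tumours, so these differences are falls in SKOV3 of genes that could hardly fall in OVCAR8. Both groups of at least 1 line were dim in 257 of the 909 genes and 612 of the 3178. As many genes were reached by 2 of 100 splits in each case. The highest other split, which swaps control and c-Fos within 1 line, gave 1266 for the real 909 and 4314 for the real 3178, and the next gave 412 and 2603. For the comparisons of 3 against 3 arrays, 10 splits cannot give a share under 0.05, and 1 of 10, the real split, reached the count in each: the real values were 1655, 461, 5178, 1409, 3080, 8410, 1623 and 575, and the highest other value was 0 in all but OVCAR8 tumours with c-Fos, where it was 1.

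Changes with c-Fos in SKOV3 tumours run together along chromosomes. Over 212 windows of 25 to 50 neighbouring genes the window medians had an SD of 0.2342, against at most 0.0847 in 100 shuffles. A property of the tumour samples alone is excluded by its test, since 10 of the 10 most extreme tumour windows lay outside the shuffled range on the same side in culture (2 of the 10 hold only 25 and 26 genes). To give the ERBB2 fall of 1.93, OVCAR8 control cells must be at least 73.8% of these tumours, the share needed if they add no ERBB2 transcript. The 22 genes at least 16-fold higher in OVCAR8 would then rise by at least 3.59. Their median was 0.83 and quartiles 0.19 and 2.56, which argues against these cells. OVCAR8 c-Fos cells were not tested. Different copy numbers in SKOV3 c-Fos cells met their prediction (culture window SD 2.89 times the highest shuffle, 0.2100 against 0.0728 without the narrow array). OVCAR8 met it too (tumours 2.08, cultures 1.57), so it cannot decide. Copy number was not measured.

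SKOV3 culture c-Fos replicate 1 has a narrow range of values. Its deviation from replicates 2 and 3 had a slope of −0.52 on their mean, against −0.08 to 0.04 for the other arrays, which explains nothing. A sample of another of the 8 groups, or from elsewhere, under this label stays open. Its correlation with its own group's deviations was 0.15, 0.08 above the best other group. Over 200 resamples this was 0.055 to 0.106, which gives no spread between arrays. The array hardly matches its own group, as the other arrays have 0.71 to 0.96 with theirs. What narrowed the range was not tested.

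MYF5 and ASB5 are high in SKOV3 c-Fos tumour replicates 1 and 3 (MYF5 12.6 and 12.5, ASB5 11.6 and 12.1) and lower in replicate 2 (6.1 and 8.3). Mature host skeletal muscle is argued against as their main source, as far as mouse transcripts bind this human array alike. Over 20 muscle genes the median change was 0.38 and the upper quartile 0.69, against 5.23 for MYF5. ACTA1 (0.37) hardly moved, but 6 of the 20 rose. The first 17 reached at most 0.79 (TNNI2, called). MYPN (4.28, and 3.12 in OVCAR8 tumours), CHRNA1 (3.08) and DES (1.63) were added because they were called. Immature muscle cells stay open. DES (9.90, 7.81 and 9.40 in replicates 1, 2 and 3), CHRNA1 (10.12, 6.23 and 10.40) and leukocyte PTPRC (6.24, 4.33 and 8.55) were lowest in replicate 2 as well. MYOD1 (5.80, 5.94 and 6.06) and MYOG (7.00, 7.07 and 7.31) were not. In culture c-Fos replicates 2 and 3 MYF5 was −0.16 from control, which excludes a raised MYF5 level there but not a small share of cells that express it. ASB5 was 0.51 above control there, which leaves the same question open for ASB5. No other biological explanation was tested.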

How the results depend on the processing

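Fits without SKOV3 culture c-Fos replicate 1 were in part chosen only after the results were seen. With 3 arrays per group the count of changed genes depends strongly on how variance is shared, and the cause was not tested for the moved values that follow unless stated.

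With only the arrays of the compared groups the counts were 343 for c-Fos in SKOV3 cultures, 8394 in OVCAR8 cultures, 3344 in SKOV3 tumours and 2625 in OVCAR8 tumours, 11569 for lines in culture, and 4347 and 6409 for tumour against culture in SKOV3 and OVCAR8. By construction this takes the narrow array out of every fit but the first. With all 24 arrays in 1 fit the c-Fos counts were 4497, 775, 2949 and 659 in the same order, and the differences of effects 1820 in culture and 1702 in tumours. ArrayWeights gave 9508 for SKOV3 cultures, 9009 for OVCAR8 cultures, 3378 for OVCAR8 tumours, 11883 for lines in culture, 8050 and 7913 for tumour against culture and 9371 for the culture difference of effects. Quantile normalization gave 759 for OVCAR8 cultures and 1374 for the culture difference of effects. The replicate block gave 945, 170 and 403 for SKOV3 cultures, OVCAR8 cultures and the culture difference of effects, and moved no other count by over 1.5 times. Same-number correlations were −0.17, −0.07 and −0.05 in SKOV3 cultures, 0.04, −0.09 and −0.02 in OVCAR8 cultures, 0.13, 0.01 and 0.04 in SKOV3 tumours and −0.33, −0.26 and −0.29 in OVCAR8 tumours.

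Leaving out 1 array gave these lowest and highest counts: SKOV3 cultures 929 to 7652, OVCAR8 cultures 187 to 5533, SKOV3 tumours 3993 to 5239, OVCAR8 tumours 637 to 1086, lines in culture 2072 to 9953, lines in tumours 6885 to 7875, tumour against culture 1023 to 4797 in SKOV3 and 252 to 3119 in OVCAR8, and differences of effects 537 to 6362 in culture and 2286 to 3319 in tumours. Each highest culture value is without SKOV3 culture c-Fos replicate 1.

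Lists called with an estimated correlation were 1 of the 8 for SKOV3 cultures, 0 of 5 for OVCAR8 cultures, 0 of 6 for SKOV3 tumours, 0 of 7 for OVCAR8 tumours, 0 of 7 and 0 of 5 for lines in culture and tumours, 2 of 7 and 1 of 8 for tumour against culture in SKOV3 and OVCAR8, and 0 of 5 and 0 of 10 for the differences of effects. Fry called 13, 3 and 14 in SKOV3 cultures, OVCAR8 cultures and SKOV3 tumours, 16 for lines in tumours, 2 for OVCAR8 tumour against culture and 8 for the culture difference of effects. Without SKOV3 culture c-Fos replicate 1, 11 lists were called in SKOV3 cultures, 8 in OVCAR8 cultures and 9 for the culture difference. The only list that reversed was cholesterol synthesis in SKOV3 cultures, upward with adjusted p = 0.969 without that array. The balance of called genes also turned without it, to 4798 higher and 2854 lower in SKOV3 cultures, 2921 and 2612 in OVCAR8 cultures, 5196 and 4757 for lines in culture, and 2798 positive and 3564 negative for the culture difference of effects. ArrayWeights turned the same 4. Centred arrays gave 710 and 642 in OVCAR8 tumours.

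At adjusted p under 0.01 the shared genes were 6 higher and 57 lower between lines in culture, 39 and 99 in tumours, 101 and 427 between culture and tumour in SKOV3 and 25 and 62 in OVCAR8. Without the narrow array they were 1196 and 792 between lines in culture, 1031 and 1523 in SKOV3 and 401 and 538 in OVCAR8. Of 749 values for named genes, 42 lost their call with only the arrays of the compared groups, 49 with the replicate block, 31 with centred arrays, 24 with quantile normalization, 5 with the mean of probe sets and 3 each with an intensity trend and arrayWeights. All 24 arrays in 1 fit cost 39 of 584, the dim filter 0 of 733 and leaving out 1 array 570 of 4960.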

Other observations

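The set of genes called in all 4 c-Fos comparisons and the test of each of its genes with single arrays left out were chosen only after the results were seen.

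Called the same way in all 4 c-Fos comparisons were 7 higher and 38 lower genes, with culture calls limited by the narrow array. Independence, which shared variances break, gives 0.02 and 0.13. Each array of each fit was then left out in turn, 48 settings per gene. Of the 7, FOS and MARCHF4 (2.27 in SKOV3 cultures, 2.74 in OVCAR8 cultures, 1.17 in SKOV3 tumours and 2.60 in OVCAR8 tumours) kept every call. Of the 38, 10 kept every call: the hypoxia-responsive factor EPAS1 (−3.28, −2.10, −3.50 and −1.65), the secreted guidance protein SEMA3A (−5.15, −1.24, −3.71 and −1.48), AMIGO2, KAZN, LIMCH1, LRATD2, P3H2, PDGFRL, PRICKLE1 and ZMAT1. The other 5 and 28 lost a call in at least 1 setting, 56 of all 180 calls. Among these are versican VCAN (−5.89, −2.88, −4.12 and −1.75), without any 1 OVCAR8 tumour array in OVCAR8 tumours (adjusted p up to 0.119), and the integrin chain ITGB8 (−2.13, −3.22, −3.12 and −1.07), without OVCAR8 tumour control replicate 2 (0.0547). Fibronectin FN1 (−2.85, −2.21, −1.33 and −1.66) lost its call in OVCAR8 cultures in 9 settings (up to 0.131), but had adjusted p = 8.95e-09 there at the same −2.21 without the narrow SKOV3 array.

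In SKOV3, window medians of the c-Fos effect in tumours and cultures correlated at 0.65, against at most 0.41 in shuffles. Chromosome 13 lay up as a whole (median 0.72 in tumours and 0.61 in cultures), and chromosomes 15 (−0.46 and −0.31) and 22 (−0.55 and −0.22) down. On chromosome 17 the window from TOP3A to CPD lay at −0.93 and −0.56. The window that holds ERBB2, from PSMB3 to STAT5B, lay at −0.38 and −0.23, outside the central 95% of shuffled windows but not among the 10 most extreme. Genes next to ERBB2 changed unevenly: PPP1R1B (−2.32 in tumours and −2.64 in cultures), ERBB2 (−1.93 and −1.47), GRB7 (−3.35 and −1.54) and IKZF3 (−1.59 and −0.51) fell, while MIEN1 (0.13 and −0.05) between them hardly moved. Culture values here are without the narrow array. One reading is that the SKOV3 c-Fos clones differ from control cells in chromosome numbers. The uneven fall around ERBB2 would then need a further cause. As stated, the culture window SD cannot decide this reading. Part of the SKOV3 c-Fos effect may be a clone difference, which DNA of the clones could settle.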
